A study of Mus musculus with 16 samples.

How the data were processed

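RNA was measured in natural killer (NK) cells (live CD45+ CD3- NKp46+ DX5+ cells) sorted from the axillary tumour-draining lymph nodes (LN) and from the lungs of mice bearing transplanted mammary tumours, in which cells that express Foxp3 carry the diphtheria toxin (DT) receptor. There are 16 libraries in 4 groups of 4: LN and lung, each from mice given DT or PBS. The design text states 4 biological replicates per group, and the p-values below take each library as one animal. Per the submitters' processing notes, reads were aligned with HISAT2 to GRCm38 and counted per gene with HTSeq; the versions of both tools are not given in the sources used here. The table the authors deposited holds raw counts per gene for 49671 Ensembl genes, and every value in it is a whole number of 0 or more. All 16 columns were used and none was left out. Gene symbols, coordinates and biotypes come from an Ensembl annotation of GRCm38.

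Total counts per library lay between 3929560 and 10744934. Genes were kept where filterByExpr of edgeR, by group and with its default minimum count of 10 and minimum total of 15, kept them, which left 13940. Counts were scaled by TMM and fitted in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood method (robust=TRUE) in a single model of 4 group means with 12 residual degrees of freedom and a common biological coefficient of variation of 0.621. The contrasts, tested with two-sided F tests, were 4: DT against PBS in LN, DT against PBS in lung, the first of these minus the second (the interaction), and lung against LN in mice given PBS. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all tested genes are called higher or lower. Values per group are CPM on TMM-scaled library sizes as mean ± SD with n = 4. Errors of log2 fold changes are the standard errors (SE) implied by the F statistic.

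There were 35 gene lists with 615 symbols, all found in the table: 21 of NK cells, responses, cell cycle and metabolism, and 14 of other cell types. The 26 lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists within a comparison. The same test with the correlation between members estimated from the data, and fry (limma), are given as well. The counts adjusted over the list alone take a list's own members as the set of tests. Values per library (lists of other cell types, quality measures and mean list levels) were compared by exact two-sided permutation tests, for which 4 against 4 libraries give a smallest p of 0.0286. The lists, the comparisons and the rule for naming genes were set before the data were examined. So were the edgeR and camera tests and the permutation tests of the lists of other cell types.

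The genes named are, per comparison, those called with a mean of at least 10 CPM in the higher group and no overlap between the libraries of the 2 groups. Predicted genes, immunoglobulin and T cell receptor segments and markers of other cells were left out, and at most 10 were taken in each direction. Where fewer than 5 passed, those of smallest p were added and are given as not passing. From each list the 3 members of smallest p are named, together with 15 fixed genes; genes outside this rule are said to be chosen after the values were seen. A few genes that the rule names are not reported here. Where a group has no counts, the fold is a lower bound against a floor of 3 counts over the summed libraries of the group. With 1 to 3 counts the ratio of summed counts is given with its 95% counting interval. These intervals and floors cover counting error only. With members at 0 in a group set to that bound, the median of the neutrophil list between the tissues moves from 4.14 to 4.13. That of every other list tested with camera stays as given in the comparisons of 2 groups. The medians of the interaction were not recomputed.

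The tests were tested on simulated data: counts were drawn gene by gene, independently, with 1 mean level per gene and the dispersions and sizes of these libraries, and 200 genes were changed by 2-, 4- or 8-fold. For LN the calls recovered 3.03%, 43.3% and 57.8% of the changed genes at these sizes, with 0 false calls. For lung they recovered 1.49%, 42.4% and 70.8% with 3 false calls, for the interaction 1.52%, 9.38% and 35.4% with 2, and for the tissues 1.54%, 32.3% and 58.7% with 0. When the mitosis list was doubled in the simulated counts, camera called it at adjusted p of 2.42e-14, 1.71e-11, 6.32e-12 and 1.34e-14 in the same order. Of the other lists it called 0, 0, 1 and 0. In the real data members of a list can correlate, for the mitosis list by an estimated 0.325 in LN and 0.342 in lung. The simulated genes did not, so these counts do not show how often camera calls lists falsely here.

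The alternatives tried were median-ratio size factors, total counts alone, robust=FALSE, no gene filter, a mean of at least 5 CPM, the replicate number as a block, the Wald test of DESeq2 1.42.0, limma-voom with sample quality weights, only the 8 libraries of the groups compared, and each library left out in turn. Chosen after the libraries were seen were 2 more: leaving out both DT libraries numbered 1, and the mitochondrial share of counts as a covariate. That share went largely with DT. It ran from 3.11 to 4.40% in lung DT and from 0.951 to 2.57% in lung PBS. In LN DT it ran from 1.24 to 4.93% and in LN PBS from 1.05 to 1.68%. Results with this covariate therefore cannot tell RNA quality from DT. With total counts alone in place of TMM, the median log2 fold change of the tissue comparison moves by -0.168. Exon length (all exons of a gene merged) was compared with the fold change in 5 equal groups of the tested genes with a known length (99.9% of them). Lungs were digested with enzyme at 37 °C and treated to lyse red cells while the lymph nodes are not said to be, so tissue and preparation cannot be separated.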

Results

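NK cells were sorted from the tumour-draining lymph nodes (LN) and the lungs of mice with mammary tumours, and RNA was counted in 16 libraries. Mice were given DT, whose receptor is carried by Foxp3-expressing cells, or PBS, and each of the 4 groups (LN PBS, LN DT, lung PBS, lung DT) has n = 4. The comparisons ask what DT changes in NK cells of each tissue, whether the 2 responses differ, and how lung and LN NK cells differ without DT. Total counts per library ran from 3929560 (lung PBS replicate 2) to 10744934 (lung PBS replicate 1), and 13940 of 49671 genes could be tested.

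The genes of the sort gate were abundant in every group. Ncr1, which encodes NKp46, stood at 5965 ± 429 CPM in LN PBS, 6079 ± 1247 in LN DT, 4656 ± 670 in lung PBS and 3289 ± 957 in lung DT (SD, n = 4). Ptprc, which encodes CD45, had means of 3938, 6141, 4593 and 5743 CPM in the same order, and Itga2, the DX5 antigen, 76.9, 101.2, 113 and 106 CPM. Cd3e, the gate's negative marker, had 18.9 ± 9.46 CPM in LN PBS and 1.24 ± 1.29 in lung PBS (adjusted p = 0.0977). Foxp3 had at most 9 counts in any library and too few to be tested.

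The first 3 principal components held 27.2%, 18.3% and 12.2% of the variance. All 8 LN libraries lay below 0 on the first component and all 8 lung libraries above it. LN DT replicate 1 and lung DT replicate 1 stood apart on the second, at 108 and 152, with every other library at 19.6 or lower. On the third, LN DT replicates 1 to 3 lay at -72.6, -74.0 and -71.5 and lung DT replicates 2 and 3 at -55.4 and -54.8. LN DT replicate 4 (3.55) and lung DT replicate 4 (14.4) lay nearer to their PBS groups. Lung DT replicate 1 (32.9) lay within the range of lung PBS (25.3 to 59.8). LN DT replicate 1 and lung DT replicate 1 also had the highest Malat1 (18216 and 17164 CPM; others at most 8511) and mt-Cytb (32039 and 21697; others at most 8589).

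In LN, what DT changes in NK cells was asked first. With DT 9 genes were higher and 0 lower: Lilrb4a, Cd300lf, Rgs1, Ttn, AI593442, E2f7 and 3 genes of antibody-secreting cells. The last 3 go with the rise of plasma cell genes described below, so not every call can be credited to NK cells. Whether RNA of other cells in the sort holds part of the other calls was not tested. The lists of mitosis genes and inhibitory receptors rose, as did those of B cells and dendritic cells, and the list of immature NK markers fell. With an estimated correlation the mitosis and inhibitory receptor lists (both adjusted p = 0.24), B cells (0.519) and dendritic cells (0.377) did not pass. The immature list did (adjusted p = 0.0249). In fry the mitosis and inhibitory receptor lists (both adjusted p = 0.0395) and the immature list (0.00678) passed. B cells (fry adjusted p = 0.228) and dendritic cells (0.0906) did not. Lilrb4a, an inhibitory receptor of the immunoglobulin family, rose by 2.63 ± 0.41 on the log2 scale (SE, n = 4; adjusted p = 0.0131), from 27.7 ± 6.18 to 172 ± 72.9 CPM (SD). Rgs1, a brake on chemokine receptor signalling, rose by 2.52 ± 0.39 (adjusted p = 0.0131), from 74.4 ± 17.9 to 427 ± 181 CPM. Cd300lf, a receptor of membrane lipids, rose by 1.62 ± 0.25 (adjusted p = 0.0131), from 36.6 ± 4.89 to 113 ± 17.6 CPM. Ttn, known for the muscle protein titin, rose by 2.69 ± 0.38 (adjusted p = 0.0109), from 12.6 ± 4.92 to 81.5 ± 24.7 CPM. AI593442 had 598 counts in the LN DT libraries against 1 in LN PBS, a ratio of 673 with a counting interval of 120 to 26600 (adjusted p = 0.0157).

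By tool, edgeR called 9 genes higher and 0 lower, with 1155 and 491 at an unadjusted p under 0.05 against 697 by chance in both directions together. DESeq2 called 262 and 61, and limma-voom with quality weights 2084 and 1652. The libraries of the 2 groups did not overlap for 704 genes with higher and 477 with lower values in DT, 8.47% of genes where chance gives 2.86%. The calls depend on single libraries: without LN PBS replicate 3 or 4 there were 0, and without LN DT replicate 4 there were 74 higher and 48 lower. With the mitochondrial share as a covariate none of the 9 remained called. Ttn then had 2.32 (adjusted p = 0.227, within 2.60e-08 to 0.227 over all alternatives). That share was mostly higher with DT, so the lost calls cannot tell RNA quality from DT.

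The called genes lie on GRCm38 as protein_coding genes: Lilrb4a (ENSMUSG00000062593) on chromosome 10 from 51480679 to 51496613, Rgs1 (ENSMUSG00000026358) on 1 from 144242296 to 144249242, Cd300lf (ENSMUSG00000047798) on 11 from 115116214 to 115133992, Ttn (ENSMUSG00000051747) on 2 from 76703980 to 76982547, and AI593442 (ENSMUSG00000078307) on 9 from 52673042 to 52679780. Chosen after the values were seen, the other called genes are 3 of antibody-secreting cells and a cell cycle regulator. Ighe had 3537 counts against 1 (ratio 3980, interval 714 to 1.57e+05; adjusted p = 0.00805) and Jchain 5932 against 2 (ratio 3340, interval 924 to 27600; adjusted p = 0.0244). Ighg1 rose from 0.714 ± 1.19 to 301 ± 188 CPM (SD; adjusted p = 0.0251). E2f7, a repressor of the cell cycle, had 192 counts against 3 (ratio 72.0, interval 24.3 to 352; adjusted p = 0.0270).

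The mitosis and G2/M list rose in LN DT with a median log2 fold change of 1.18: 31 of 33 members lay above 0 and 2 below (camera adjusted p = 5.30e-11; adjusted p = 0.24 with an estimated correlation). No member was called over all genes and 4 were adjusted over the list alone; Mki67 had 1.94 (adjusted p = 0.0893), the kinesin gene Cenpe 2.74 (0.0956) and Top2a 1.71 (0.172). The DNA replication list rose as well, with 22 of 32 members above 0, a median of 0.39 and 3 members higher adjusted over the list alone (camera adjusted p = 0.0454; adjusted p = 0.53 with an estimated correlation). Its members of smallest p were Tyms (2.19, adjusted p = 0.139), Pola1 (1.33, 0.151) and Clspn (2.58, 0.204). The DNA replication call ended, with camera adjusted p up to 0.182, without LN PBS replicate 1 (0.0725), 2 (0.128) or 4 (0.138), LN DT 3 (0.0967) or 4 (0.182), lung PBS 1 to 4 (0.0571, 0.0653, 0.0682, 0.0578) or lung DT 2 to 4 (0.0568, 0.052, 0.075), and with total counts alone (0.05). It passed in 9 of 22 alternatives, with adjusted p from 7.39e-04.

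Inhibitory receptors rose as a list: 12 of 15 lay above 0 and 3 below, with a median of 0.78 and 5 higher adjusted over the list alone (camera adjusted p = 0.00131; adjusted p = 0.24 with an estimated correlation). Klrg1, a receptor of mature NK cells, stood at 387 ± 67.1 against 179 ± 47.4 CPM (SD, n = 4; adjusted p = 0.177), Tigit at 240 ± 172 against 66.1 ± 22.7 (0.18) and the ectonucleotidase gene Entpd1 at 105 ± 67.6 against 41.8 ± 10.7 (0.185). The interferon gamma list rose with 20 of 26 members above 0, a median of 0.25 and 3 higher adjusted over the list alone (camera adjusted p = 0.0454; adjusted p = 0.377 with an estimated correlation). Gbp8 had 2.95 (adjusted p = 0.0725), Ly6a 4.26 (0.0820) and Gbp4 1.18 (0.172). The interferon gamma call passed in 11 of 22 alternatives (camera adjusted p from 7.39e-04 to 0.338) and ended without LN PBS replicate 1 (0.0565), 2 (0.0508) or 4 (0.138), LN DT 4 (0.338), lung PBS 1, 3 or 4 (0.0563, 0.0682, 0.0557) or lung DT 1 to 3 (0.081, 0.0568, 0.052), and with total counts alone (0.055).

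The immature CD27-positive marker list fell: 13 of 16 members lay below 0 and 3 above, with a median of -0.60 (camera adjusted p = 1.48e-04; adjusted p = 0.0249 with an estimated correlation). Ltb, a cytokine gene of lymphoid organisation, stood at 473 ± 169 against 981 ± 148 CPM (adjusted p = 0.177) and Tcf7, a factor of early NK cells, at 95.7 ± 43.3 against 242 ± 40.5 (0.211), while Ctla2a was above its PBS level with 1.19 (0.231). Adjusted over the list alone, 1 member was higher and 2 were lower. Trafficking and adhesion genes fell with 16 of 22 below 0, a median of -0.48, and 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00407; adjusted p = 0.377 with an estimated correlation). S1pr1, the receptor for exit from lymph nodes, had -1.35 (adjusted p = 0.172) and Itgb1 -1.29 (0.216). With the mitochondrial share as a covariate the trafficking list did not pass and the test pointed up (0.857; 4.14e-04 to 0.857 over all alternatives). With an estimated correlation the immature list passed in 13 of 22 alternatives, within 0.0145 to 0.0922. Among the other 9 were those without LN DT replicate 2 (0.0503) or 3 (0.0695), lung PBS 2 (0.0602) or 3 (0.0601) and lung DT 1 (0.0922) or 4 (0.0822), without both DT libraries numbered 1 (0.0876) and with that covariate (0.0511).

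Glycolysis fell in LN DT with a median of -0.49 (camera adjusted p = 0.00407; adjusted p = 0.547 with an estimated correlation), with Eno1 at -1.01 (adjusted p = 0.272), Hk2 at 1.66 (0.449) and Pgk1 at -0.49 (0.519). MYC and ribosome biogenesis fell with a median of -0.32 (camera adjusted p = 0.0202; adjusted p = 0.24 with an estimated correlation), with Eif4a1 at 0.85, Tfrc at 1.53 and Slc3a2 at -0.55. Immediate early genes fell with a median of -0.30 (camera adjusted p = 0.0454; adjusted p = 0.547 with an estimated correlation), with Dnajb1 at -1.04, Klf6 at -0.62 and Nfkbia at -0.51. None of the members of these 3 lists was called over all genes or adjusted over the list alone. With the mitochondrial share as a covariate glycolysis rose (camera adjusted p = 0.00562; 9.11e-06 to 0.103 over all alternatives), and it did not pass without LN DT replicate 1 (0.091) or both DT libraries numbered 1 (0.103). MYC (0.0028 to 0.101) did not pass without LN PBS replicate 2 (0.0508), at a mean of at least 5 CPM (0.101) or with that covariate (0.0609). Immediate early genes (0.0143 to 0.613) did not pass without LN PBS 2 (0.295), LN DT 1 (0.0872), LN DT 3 (0.072) or both DT libraries numbered 1 (0.0902). They also missed it at a mean of at least 5 CPM (0.148), with total counts alone (0.05) and with that covariate, where their test pointed up (0.613).

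The cytotoxic effector list did not pass (median 0.07, camera adjusted p = 0.569), and its members went both ways. It rose with the mitochondrial share as a covariate (camera adjusted p = 0.004; 0.004 to 0.86 over all alternatives). Gzmb stood at 1694 ± 571 against 681 ± 269 CPM (SD, n = 4; adjusted p = 0.139) and Gzma at 20540 ± 11150 against 6282 ± 2389 (0.151), while Gzmm had 21.3 ± 4.34 against 64.4 ± 14.4 (0.0981). Prf1 (0.10, adjusted p = 0.964) and Ifng (0.75, 0.595) stayed nearer to PBS levels. Il10 had 178 counts in LN DT and none in LN PBS, at least 66.8-fold higher (adjusted p = 0.139), in a cytokine list that did not pass (0.391). Il2ra, the high-affinity interleukin 2 receptor chain, had 37.1 ± 12.7 against 7.84 ± 0.820 CPM (adjusted p = 0.108) and Ccnd2 504 ± 206 against 1235 ± 302 (0.104).

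Other lists that did not pass were activating receptors (camera adjusted p = 0.384), cytokine receptors (0.917), STAT5 targets (0.384), type I interferon genes (0.53), oxidative phosphorylation (0.109; past downward in 4 of 22 alternatives, 0.00223 to 0.428), mature NK markers (0.0957; past upward in 3, 1.40e-04 to 0.566), ILC1 markers (0.0957; past upward in 6, 0.0255 to 0.209), transcription factors (0.191, past downward in 1, 0.0487 to 0.399) and TGF-beta genes (0.384). Cytokine receptors (6.19e-04) and STAT5 targets (1.40e-04) rose with the mitochondrial share as a covariate, where the ranges over all alternatives end at 0.998 and 0.848. STAT5 targets also did without both DT libraries numbered 1 (0.0352). Cholesterol synthesis (0.569) had a median of -0.01 and a mean of 0.14 with the test pointing down. ILC1 markers held 1 called gene, Rgs1, next to Itgae (1.22, adjusted p = 0.361) and Cxcr6 (1.45, 0.415). Below their PBS levels but not passing were Cym (-2.02, adjusted p = 0.0766), Ifitm10 (-1.36, 0.0956) and Ssbp2 (-1.70, 0.0981).

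Markers of other cells were measured in LN as well. The summed plasma cell list stood at 284 ± 164 against 6.92 ± 2.80 CPM (exact two-sided permutation p = 0.0286, the smallest possible; adjusted 0.24), with Jchain at 201 ± 109, Iglv1 at 46.4 ± 34.1 and Mzb1 at 34.3 ± 30.9 CPM in LN DT. B cell genes rose as a list with 16 of 17 above 0, 3 higher adjusted over the list alone and a median of 1.82 (camera adjusted p = 1.11e-04; adjusted p = 0.519 with an estimated correlation), led by H2-Ab1 at 437 ± 225 against 132 ± 25.9 CPM. With the mitochondrial share as a covariate the B cell list had a camera adjusted p of 0.0731 (3.62e-07 to 0.0731 over all alternatives). Dendritic cell genes rose with 9 of 9 above 0 and a median of 3.62 (camera adjusted p = 0.00447; adjusted p = 0.377 with an estimated correlation), with Siglech at 69.8 ± 92.7 against 1.71 ± 1.41 CPM. T cells (0.384), macrophages (0.391) and neutrophils (0.545) did not pass. Macrophages rose without LN PBS replicate 3 (0.0149, within 0.0149 to 0.821 over all alternatives). The mitochondrial share of counts was 3.59 ± 1.62% against 1.4 ± 0.292% (exact permutation p = 0.114), and Xist had 890 against 375 CPM (exact permutation p = 0.0571). No quality measure passed in LN (exact permutation tests, adjusted p from 0.143 to 0.171).

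The lung comparison asked the same of NK cells at a distant site. In the sorted lung cells 8 genes were higher and 7 lower with DT, and 4 of the higher genes act in cell division: Mki67, Cit, Knl1 and Top2a. The calls fell to 0 higher and 1 lower, Zfp882, with the mitochondrial share as a covariate. Mki67 then had 2.35 (adjusted p = 0.429, within 5.56e-09 to 0.429 over all alternatives). That share was higher in every lung DT library than in any lung PBS library, so the lost calls cannot tell RNA quality from DT. Mki67, the marker of cycling cells, rose by 2.90 ± 0.42 on the log2 scale (SE, n = 4; adjusted p = 0.0129), from 20.5 ± 6.96 to 154 ± 66.3 CPM (SD). Cit, a kinase of cytokinesis, rose by 2.99 ± 0.48 (adjusted p = 0.0162), from 12 ± 1.55 to 95.4 ± 50.7 CPM. Knl1, a kinetochore scaffold, rose by 2.82 ± 0.46 (adjusted p = 0.0162), from 7.70 ± 2.87 to 54.8 ± 17.9 CPM. Top2a, the topoisomerase of dividing cells, rose by 2.48 ± 0.47 (adjusted p = 0.0491), from 30.9 ± 9.53 to 173 ± 140 CPM. Nav2, a neuron navigator gene, rose by 3.27 ± 0.53 (adjusted p = 0.0162), from 1.78 ± 0.582 to 17.3 ± 5.52 CPM.

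Ttn rose in lung by 2.60 ± 0.39 (SE, n = 4; adjusted p = 0.0158), from 3.44 ± 0.338 to 20.9 ± 8.77 CPM (SD), and Lilrb4a by 2.21 ± 0.40 (adjusted p = 0.0342), from 58.1 ± 27.1 to 267 ± 114. H2-Q10, a class I gene, rose by 1.46 ± 0.26 (adjusted p = 0.0342), from 26 ± 6.15 to 71.4 ± 9.74 CPM. Cym, the gene of the protease chymosin, fell by 2.60 ± 0.41 (adjusted p = 0.0162), from 77.7 ± 29.1 to 12.8 ± 4.78 CPM. Zfp882, a zinc finger gene, had 2 counts in lung DT against 528 in lung PBS, a ratio of 262 with an interval of 72.3 to 2170 (adjusted p = 0.00419). Chosen after the values were seen, the other 5 lowered genes are of low level: Parp16 with 1 count against 132 (adjusted p = 0.0162), Dctd with 2 against 85 (0.0312), Lrrc20 with 2 against 94 (0.0491), Patj at 0.374 against 7.30 CPM (0.0327) and Cpne4 at least 17.6-fold lower (0.0327). Near the threshold but not passing were Angpt1 (-4.86, adjusted p = 0.0565), Cyp20a1 (-1.64, 0.0623) and Acat1 (-1.23, 0.0680).

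Their places on GRCm38, all protein_coding, are Mki67 (ENSMUSG00000031004) on chromosome 7 from 135689784 to 135716361, Cit (ENSMUSG00000029516) on 5 from 115845278 to 116008947, Knl1 (ENSMUSG00000027326) on 2 from 119047119 to 119105501, Top2a (ENSMUSG00000020914) on 11 from 98992943 to 99024189, Nav2 (ENSMUSG00000052512) on 7 from 48908716 to 49610090, H2-Q10 (ENSMUSG00000067235) on 17 from 35470089 to 35474563, Cym (ENSMUSG00000046213) on 3 from 107211293 to 107221732 and Zfp882 (ENSMUSG00000089857) on 8 from 71908608 to 71916354. In edgeR 1068 genes had an unadjusted p under 0.05 with higher and 984 with lower values; DESeq2 called 275 and 181, and limma-voom with quality weights 251 and 184. Libraries did not overlap for 467 higher and 631 lower genes, 7.88% where chance gives 2.86%. Fitted on the 8 lung libraries alone, edgeR called 0 genes, and without lung PBS replicate 1 or 2 it called 0 higher and 1 lower. Without lung DT replicate 4 it called 49 and 80, and without both DT libraries numbered 1 it called 169 and 305.

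The mitosis and G2/M list rose in lung with 30 of 33 members above 0 and 3 below, a median of 1.81, 2 members called over all genes and 17 higher adjusted over the list alone (camera adjusted p = 1.51e-11; adjusted p = 0.291 with an estimated correlation). After Mki67 and Top2a, the smallest p was that of Cks1b (2.18, adjusted p = 0.0894). Without both DT libraries numbered 1 the list's median was 0.79. The DNA replication list rose with 24 of 32 above 0, a median of 0.55 and 6 higher adjusted over the list alone (camera adjusted p = 3.16e-04; adjusted p = 0.291 with an estimated correlation). Tk1 stood at 43.3 ± 7.88 against 11.7 ± 2.74 CPM (SD, n = 4; adjusted p = 0.0672), Pola1 at 54.6 ± 21.9 against 21.6 ± 1.28 (0.118) and Rrm2 at 129 ± 89.6 against 36.9 ± 14.9 (0.139).

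The interferon gamma list rose in lung with 20 of 26 above 0, a median of 0.31 and 6 higher adjusted over the list alone (camera adjusted p = 0.00239; adjusted p = 0.291 with an estimated correlation). Iigp1, an interferon-induced GTPase, stood at 33.1 ± 27.2 against 1.04 ± 0.843 CPM (adjusted p = 0.0623), Nlrc5, an activator of class I genes, at 186 ± 56.1 against 84.5 ± 12.8 (0.104) and Serpina3g at 31.6 ± 21.1 against 2.66 ± 3.42 (0.121). Type I interferon genes did not pass (median 0.37; 4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.108). They rose without lung DT replicate 4 (0.0252, within 0.0252 to 0.511 over all alternatives). Ifit1 had -3.67 (adjusted p = 0.0861), Oas3 5.42 (0.151) and Usp18 1.35 (0.156). Without both DT libraries numbered 1 the interferon gamma list had a camera adjusted p of 0.0539 (1.08e-04 to 0.0539 over all alternatives).

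Effector and receptor genes did not pass in lung. Cytotoxic effectors had a median of -0.40 with 12 of 15 below 0 (camera adjusted p = 0.0607; past the threshold in 7 of 22 alternatives, 0.00446 to 0.567), among them Cst7 (-0.55, adjusted p = 0.452), Prf1 (-0.81, 0.488) and Nkg7 (-0.54, 0.5). Activating receptors (0.155, past downward in 3 of 22 alternatives, 3.95e-04 to 0.653) held Klrb1c at 446 ± 92.8 against 951 ± 207 CPM (SD, n = 4; adjusted p = 0.122) and Fcer1g at 984 ± 189 against 1714 ± 352 (0.205). Mature markers had a median of -0.43 (0.108, past downward in 4, 0.022 to 0.567), with Ly6c2 at 269 ± 39.4 against 745 ± 244 CPM (adjusted p = 0.0680), and immature markers -0.56 (0.111), with Ltb at 46.0 ± 14.3 against 95.8 ± 20.6 (0.133). Lta had no counts in lung DT and 36 in lung PBS, at least 11.9-fold lower (adjusted p = 0.0680), in a cytokine list at 0.466.

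The remaining lung lists did not pass: glycolysis (camera adjusted p = 0.0607), oxidative phosphorylation (0.0607), MYC (0.0607), trafficking (0.12), cholesterol synthesis (0.349), cytokine receptors (0.842), transcription factors (0.51) and immediate early genes (0.51). Median, mean and test differ in sign for STAT5 targets (0.30, -0.10, test up; 0.901), ILC1 markers (0.27, 0.06, test down; 0.873), TGF-beta genes (-0.30, 0.03, test down; 0.488) and neutrophils (0.75, -0.28, test down; 0.98). For inhibitory receptors camera points up (0.893) and fry down. Several fell in some of the 22 alternatives: oxidative phosphorylation in 11 (7.79e-05 to 0.235 over all), MYC in 7 (0.00458 to 0.252), trafficking in 1 (0.0446 to 0.396) and glycolysis in 8. Glycolysis rose with the mitochondrial share as a covariate (camera adjusted p = 0.00693; 0.00693 to 0.314 over all). Of the metabolic genes, Eno1 stood at 406 ± 79.8 against 817 ± 164 CPM (SD, n = 4; adjusted p = 0.224) and Atp5b at 436 ± 126 against 879 ± 134 (0.179).

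Markers of other cells in lung did not pass as lists: T cells (camera adjusted p = 0.111), B cells (0.232), macrophages (0.367) and dendritic cells (0.367). B cell genes rose without lung PBS replicate 2 (6.08e-04) or lung DT 4 (0.00626), within 6.08e-04 to 0.847 over all alternatives. Macrophage genes rose without the same libraries (0.00982 and 0.0178, within 0.00982 to 0.908). T cell genes rose without lung DT 4 (0.0405, within 0.0405 to 0.69). The summed macrophage list stood at 5148 ± 4758 against 2016 ± 2468 CPM (exact permutation p = 0.286), with Chil3 at 2566 ± 2891 against 64.9 ± 73.9 and Lyz2 at 1773 ± 1436 against 648 ± 762. The dendritic list stood at 93.2 ± 16.6 against 50.2 ± 15.9 CPM (exact permutation p = 0.0286, adjusted 0.4). Quality measures moved with DT: the mitochondrial share was 3.75 ± 0.676% against 1.65 ± 0.686%, protein-coding genes held 93.0% against 96.0% of counts, and Xist had 1013 against 343 CPM (each exact permutation p = 0.0286, adjusted 0.0476). In both tissues the median log2 fold change was highest in the shortest of 5 equal groups of genes by exon length (0.34 in LN, 0.31 in lung) and next highest in the longest (0.17 and 0.20).

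**Figure D1:**
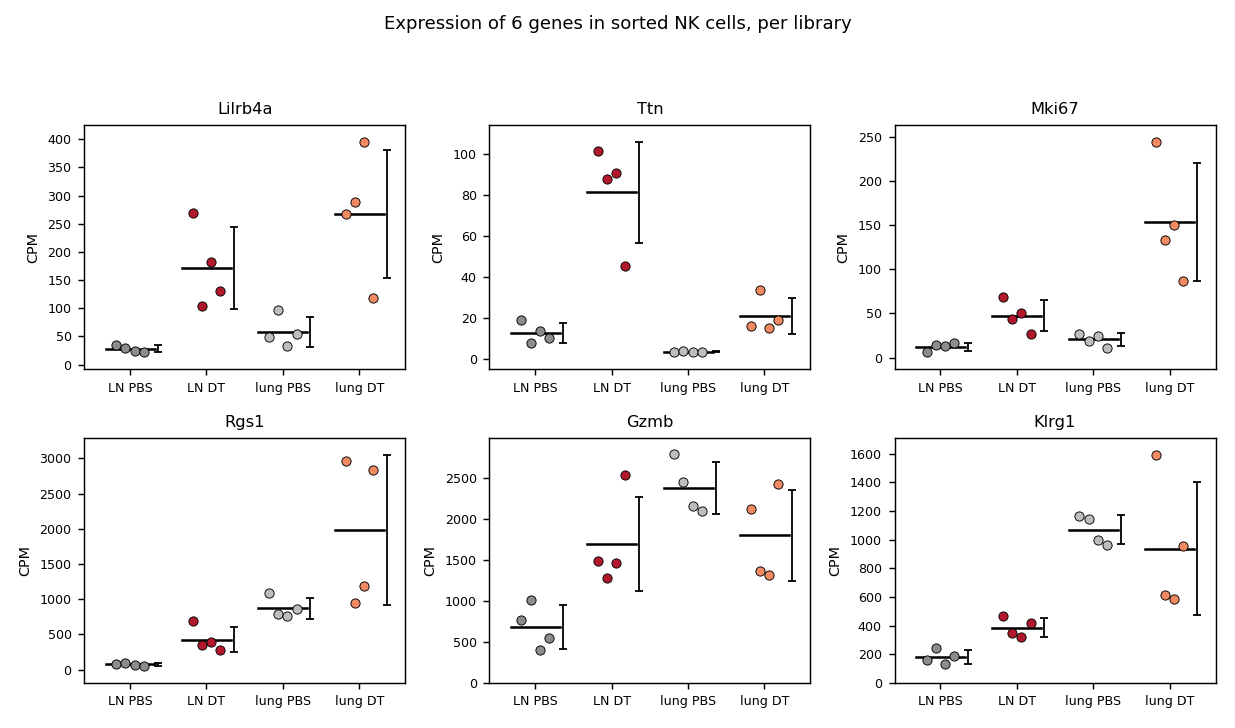
CPM per library of Lilrb4a, Ttn, Mki67, Rgs1, Gzmb and Klrg1 with the mean and SD of each group (n = 4). Lilrb4a means in PBS and DT are 27.7 and 172 CPM in LN and 58.1 and 267 CPM in lung.

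Whether the 2 tissues share a response was asked next. Lilrb4a and Ttn were called higher in both tissues, where independent calls would give 0.00517 shared genes. The labels do not say whether LN and lung libraries come from the same mice, so the 2 comparisons are not shown to be independent. The same holds for the other overlaps and the correlations. Deviations of LN DT and lung DT libraries of the same number correlated by 0.412, 0.194, 0.23 and 0.184. With the mitochondrial share as a covariate neither Lilrb4a nor Ttn was called in either tissue. The mean of that share was higher with DT in both (3.59% against 1.4% in LN, 3.75% against 1.65% in lung). Whether RNA quality contributes to the overlap and the correlations was not tested. At an adjusted p under 0.1, 7 genes were higher in both (Cit, Dtl, Gm45223, Lilrb4a, Mki67, Nav2 and Ttn) and Cym was lower in both. Across all genes, which are not replicates, the 2 log2 fold changes correlated with a Pearson r of 0.361 and a Spearman rho of 0.482, and 70.5% had the same sign. Of 570 genes with an unadjusted p under 0.05 in both tissues, 554 had the same sign.

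**Figure D2:**
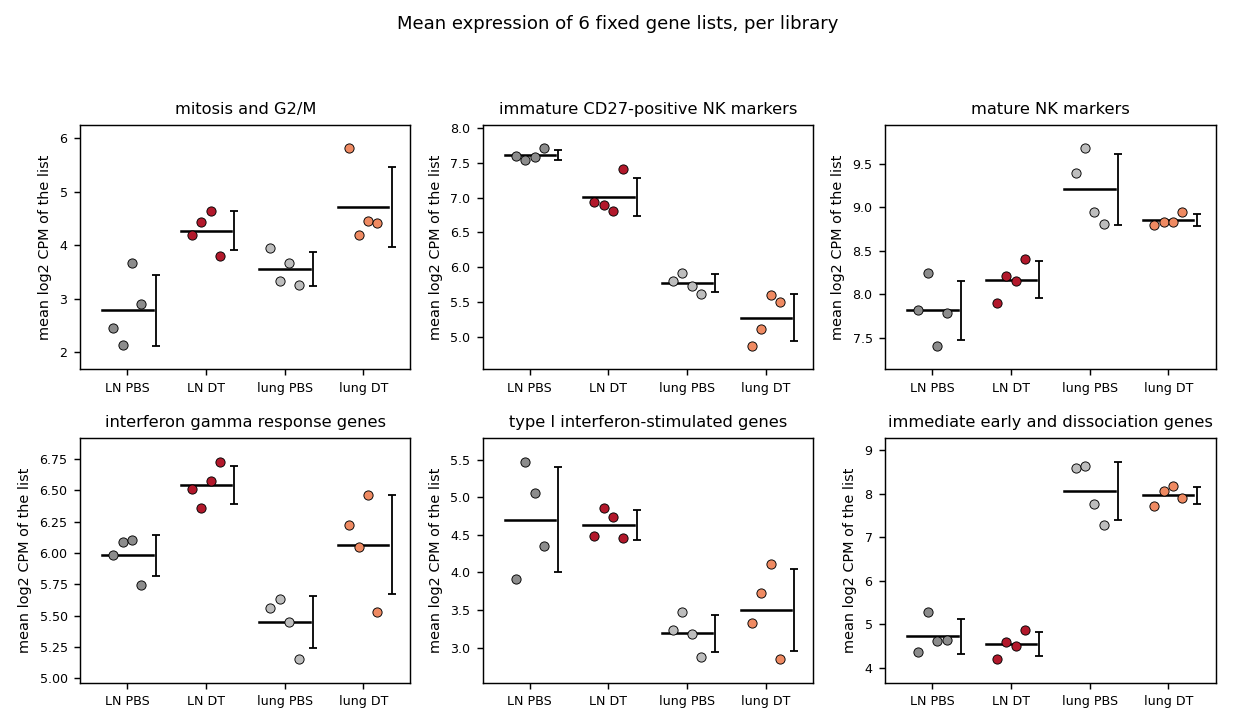
Mean log2 CPM of 6 fixed lists in each library (n = 4 per group). The mitosis list stands at 2.79 ± 0.66 in LN PBS, 4.26 ± 0.36 in LN DT, 3.55 ± 0.32 in lung PBS and 4.71 ± 0.74 in lung DT (SD).

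The difference of the responses was then tested itself. Zfp882 was the 1 gene called, with an LN response above the lung response by 8.10 ± 1.15 on the log2 scale (SE, n = 4 per group; adjusted p = 0.0215). This fitted value rests on 2 counts in lung DT, where the lung ratio of 262 has a counting interval of 72.3 to 2170, and its size is no bound. In edgeR 401 genes had an unadjusted p under 0.05 with a higher and 185 with a lower LN response, fewer than the 697 chance gives; DESeq2 called 18 and 1, limma-voom with quality weights 0 and 0, and leaving out any of LN PBS replicates 2, 3 and 4, LN DT 1 and 2, lung PBS 3 and 4 or lung DT 2 and 4 left 0. Mki67 had -0.96 (adjusted p = 1.00) and the mitosis list a camera adjusted p of 0.543. The larger lung value of that list is therefore not shown to differ from LN.

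By camera 7 lists differed between the responses, and none did with an estimated correlation or in fry. Mature NK markers had the higher LN response with 14 of 15 above 0 and a median of 0.61 (camera adjusted p = 0.00102; adjusted p = 0.294 with an estimated correlation), with Klrg1 at 1.30 (adjusted p = 0.880), Gzma at 1.65 (1.00) and Irf8 at 1.02 (1.00). Inhibitory receptors had 0.52 (camera adjusted p = 0.00726; adjusted p = 0.294 with an estimated correlation), with Entpd1 at 1.82 and Klrb1b at 1.44 (both adjusted p = 0.785). Cytotoxic effectors had 0.56 (camera adjusted p = 0.0181; adjusted p = 0.294 with an estimated correlation), with Gzmb at 1.71 (adjusted p = 0.583) and Fasl at 1.61. Cytokines had 0.25 (camera adjusted p = 0.0382; adjusted p = 0.294 with an estimated correlation), with Ccl4 at 1.84 (adjusted p = 0.415), and activating receptors 0.47 (camera adjusted p = 0.02; adjusted p = 0.595 with an estimated correlation), with Cd244 at 0.95. Single libraries ended the calls of these lists except that of mature markers. The inhibitory list did not pass without lung DT replicate 3 (0.094), the cytotoxic list without LN DT 4 (0.103) or lung DT 2 or 3 (0.0725, 0.0976), and the activating list without LN DT 1 (0.27), lung PBS 4 (0.057) or lung DT 2 to 4 (0.117, 0.156, 0.172). The cytokine list passed in 9 of 22 alternatives and did not without LN PBS 1, 3 or 4 (0.152, 0.175, 0.065), LN DT 1 to 4 (0.0576, 0.12, 0.151, 0.0649), lung PBS 1, 2 or 4 (0.137, 0.0678, 0.0715) or lung DT 2 to 4 (0.292, 0.099, 0.249). Over all alternatives the camera adjusted p ran from 1.15e-04 to 0.094 for inhibitory receptors, to 0.103 for cytotoxic effectors and to 0.27 for activating receptors, from 0.00825 to 0.292 for cytokines and from 1.24e-06 to 0.0443 for mature markers.

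Type I interferon genes had the lower LN response, with 25 of 34 below 0 and a median of -0.57 (camera adjusted p = 0.02; adjusted p = 0.595 with an estimated correlation); Oas1a had -1.81 and Ifit1 2.47 (both adjusted p = 1.00). B cell genes had the higher LN response with a median of 1.41 (camera adjusted p = 0.02; adjusted p = 0.814 with an estimated correlation). The type I interferon list did not pass without LN PBS replicate 2 (0.323), LN DT 4 (0.0523), lung PBS 4 (0.0572) or lung DT 3 (0.114). The B cell list did not pass without LN PBS 1 (0.0566), LN DT 2 or 3 (0.178, 0.202), lung PBS 2 (0.859) or lung DT 1 or 4 (0.104, 0.531). It also missed the threshold without both DT libraries numbered 1 (0.0577). The ranges over all alternatives are 9.49e-04 to 0.323 for the type I interferon list and 1.34e-04 to 0.859 for the B cell list. Of the lists that passed, members higher adjusted over the list alone were 1 cytotoxic, 2 cytokine and 3 inhibitory receptor genes. Of the other lists they were 2 STAT5 target, 2 plasma cell and 1 erythroid genes, while 1 mammary and keratin gene was lower. Not passing were ILC1 markers (0.0541; past the threshold with a higher LN response in 13 of 22 alternatives, 0.00152 to 0.172), DNA replication (0.0704), immature markers (0.0822), dendritic cells (0.0822), interferon gamma genes (0.152), immediate early genes (0.277), T cells (0.451), STAT5 targets (0.543), oxidative phosphorylation (0.59), cholesterol synthesis (0.59), cytokine receptors (0.802), neutrophils (0.856) and macrophages (0.915). DNA replication passed with a lower LN response in 4 of 22 alternatives (0.00889 to 0.703 over all) and dendritic cells with a higher one in 5 of 21 (0.0345 to 0.71). In 1 alternative each a lower LN response passed for immature markers (0.0207 to 0.306), glycolysis (0.0207 to 0.961), interferon gamma genes (0.0478 to 0.681) and immediate early genes (0.0478 to 0.937). Signs differ between median, mean and test for glycolysis (0.05, -0.01, test down; 0.59), MYC (0.01, 0.03, test down; 0.915), transcription factors (0.19, 0.01, test down; 0.59), trafficking (-0.04, 0.06, test down; 0.433) and TGF-beta genes (0.13, -0.04, test down; 0.915).

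The last comparison asked how lung NK cells differ from LN NK cells in mice given PBS. Lung NK cells had 377 genes higher and 126 lower; immediate early genes and markers of mature NK cells were higher, and markers of immature NK cells and type I interferon genes lower (for the last, adjusted p = 0.0697 with an estimated correlation). With total counts alone as the scaling the split was 298 and 229. In edgeR 1437 genes had an unadjusted p under 0.05 with higher and 912 with lower values, and the libraries of the 2 groups did not overlap for 1290 and 1382 genes, 19.2% where chance gives 2.86%. Tissue and preparation cannot be separated here, since lungs were digested with enzyme and lymph nodes are not said to be.

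Immediate early genes rose with 30 of 31 above 0, a median of 3.13, 24 called over all genes and 28 adjusted over the list alone (camera adjusted p = 1.40e-54; adjusted p = 1.23e-04 with an estimated correlation). Nr4a2, a nuclear receptor induced within minutes of stimulation, rose by 6.75 ± 0.60 (SE, n = 4; adjusted p = 4.73e-06), from 12.9 ± 4.30 to 1389 ± 271 CPM (SD), and Nr4a1 by 5.27 ± 0.49 (adjusted p = 4.73e-06), from 41.2 ± 10.5 to 1587 ± 440. Ppp1r15a, of the stress response, rose by 4.49 ± 0.39 (adjusted p = 4.73e-06) and the heat shock gene Hspa1a by 7.76 ± 1.5 (adjusted p = 0.00612). Rgs2 (4.42) and Rgs1 (3.55), both of G protein signalling, rose as well (adjusted p = 4.73e-06 and 5.49e-05).

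Mature NK markers rose with 14 of 15 above 0, a median of 1.51, 8 called and 11 adjusted over the list alone (camera adjusted p = 7.24e-14; adjusted p = 0.00803 with an estimated correlation). Klrg1 rose by 2.57 ± 0.32 (SE, n = 4; adjusted p = 1.13e-04), from 179 ± 47.4 to 1068 ± 101 CPM (SD), the transcription factor gene Irf8 by 2.34 (adjusted p = 4.28e-04) and the protease gene Cma1 by 2.38 (adjusted p = 0.00117). Immature markers fell with 14 of 16 below 0, a median of -1.63, 10 called and 12 adjusted over the list alone (camera adjusted p = 2.16e-22; adjusted p = 1.80e-05 with an estimated correlation). Ltb fell by 3.36 ± 0.31 (adjusted p = 4.73e-06), from 981 ± 148 to 95.8 ± 20.6 CPM, Il7r, the interleukin 7 receptor, by 3.63 (adjusted p = 1.52e-05), the chemokine gene Xcl1 by 2.54 (8.46e-05) and Tcf7 by 3.00 (3.65e-04). Ltb (ENSMUSG00000024399) lies on chromosome 17 from 35194439 to 35196320, Klrg1 (ENSMUSG00000030114) on 6 from 122270596 to 122282882 and Nr4a2 (ENSMUSG00000026826) on 2 from 57106830 to 57124003, all protein_coding on GRCm38.

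Type I interferon genes fell with 32 of 34 below 0, a median of -1.17, 6 called and 13 adjusted over the list alone (camera adjusted p = 1.05e-11; adjusted p = 0.0697 with an estimated correlation). Rtp4 fell by 3.58 (adjusted p = 7.69e-04), Usp18 by 2.20 (0.0035), Ifit1 by 3.99 (0.00435) and Oas3 by 5.94 (0.0390). The interferon gamma list fell with a median of -0.45 (camera adjusted p = 0.0186; adjusted p = 0.184 with an estimated correlation; 0.0518 without lung PBS replicate 4, within 0.00458 to 0.0518 over all alternatives); its member Psmb9 fell by 1.07 (adjusted p = 0.0256). Cytotoxic effectors rose with a median of 0.90, 4 higher and 1 lower over all genes and 7 and 2 adjusted over the list alone (camera adjusted p = 0.00114; adjusted p = 0.1 with an estimated correlation): Gzmb rose by 1.80 (adjusted p = 0.0035), and the granzyme inhibitors Serpinb9 by 2.43 (0.00167) and Serpinb6b by 1.37 (0.00394). Ifng rose by 2.19 (adjusted p = 0.0259) and Ccl4 by 2.76 (6.83e-05), while Csf2 fell by 4.04 (0.0162) and Lta by 4.04 (0.00615).

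TGF-beta genes rose with a median of 0.45, 3 called and 5 adjusted over the list alone (camera adjusted p = 2.33e-04; adjusted p = 0.00803 with an estimated correlation), namely Tgif1 by 2.99, Tgfb1 by 1.97 and Smad7 by 1.17 (adjusted p = 4.73e-06, 0.0133 and 0.04996). Inhibitory receptors rose with a median of 0.52 and 3 called (camera adjusted p = 0.0272; adjusted p = 0.314 with an estimated correlation), with Entpd1 up by 2.75 (adjusted p = 4.32e-04) and Klrb1b by 1.69 (0.00327). Their list did not pass without LN PBS replicate 2 (0.0675) or 4 (0.0741) or lung PBS 1 (0.0728), within 0.0112 to 0.0741 over all alternatives. Mitosis genes rose with a median of 0.73 and 1 called, Cks2 (1.76, adjusted p = 0.0122; list camera adjusted p = 0.00188; adjusted p = 0.467 with an estimated correlation). Of the receptors for migration, Cxcr6 fell by 4.14 (adjusted p = 0.00457), Cxcr3 by 3.95 (0.00857), Gpr15 by 5.14 (0.00596) and S1pr1 by 2.13 (0.00298). The trafficking and adhesion list as a whole did not pass (camera adjusted p = 0.275) and its members went both ways. Slamf6 fell by 2.82 (adjusted p = 6.49e-05), Crtam by 2.72 (0.0291), Tnfsf8 by 4.09 (0.0124), Ifi206 by 4.32 (0.0134), Tuba8 by 3.79 (0.0302) and Myc by 2.05 (0.0181).

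Lists that did not pass between the tissues were cytokines (camera adjusted p = 0.118), activating receptors (0.0722), cytokine receptors (0.0799), STAT5 targets (0.166), DNA replication (0.574), glycolysis (0.408), oxidative phosphorylation (0.471), MYC (0.0722), cholesterol synthesis (0.166), transcription factors (0.166), B cells (0.0722) and dendritic cells (0.265). Lower in lung in some of the 22 alternatives were B cells in 6 (2.81e-04 to 0.324 over all), MYC in 4 (0.016 to 0.164), activating receptors in 3 (0.0167 to 0.154) and cytokine receptors in 3 (0.0396 to 0.175). Transcription factors were higher in 1 (0.0217 to 0.49). With an estimated correlation T cell genes passed in 6 of the 22 (0.0067 to 0.0959), type I interferon genes in 3 (0.0116 to 0.192) and cytotoxic effectors in 2 (0.0161 to 0.253). ILC1 markers (median 0.11, mean -0.21, test down; 0.874) and trafficking (0.11, -0.11, test down; 0.275) differ in sign between measures. The cytokine list held 4 genes called higher and 4 lower, and trafficking 2 and 5. Insig1 (2.49, adjusted p = 4.32e-04), Bhlhe40 (2.33, 8.41e-04), Eif4a1 (1.68, 0.00507) and Pcna (1.13, 0.0310) rose within lists that did not pass.

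Genes near 0 in LN PBS led the list of the largest differences. Cxcl2, a chemokine for neutrophils, was at least 258-fold higher in lung (adjusted p = 0.00821), Trem1 at least 142-fold (0.0224) and Ptpro at least 118-fold (0.0246). Ratios with counting intervals were 421 for Inmt (75 to 16700), 370 for Adgre4 (65.9 to 14700), 268 for Casc1 (73.6 to 2220), 246 for Slamf9 (67.6 to 2030) and 246 for Lrp1 (43.7 to 9770). Markers of other cells moved with tissue: macrophage genes rose (camera adjusted p = 8.01e-06; adjusted p = 0.314 with an estimated correlation), neutrophil genes rose (1.03e-04; adjusted p = 0.141 with an estimated correlation) and T cell genes fell (2.58e-04; adjusted p = 0.0697 with an estimated correlation). NK cells express some genes of the T cell list, which Trbc1 led in LN PBS at 964 ± 129 CPM. Its fall is therefore not shown to come from T cells. Summed erythroid genes stood at 642 ± 310 against 8.05 ± 13.4 CPM (exact permutation p = 0.0286, adjusted 0.133), led by Hbb-bs at 322 ± 142 CPM, and neutrophil genes at 154 ± 144 against 6.27 ± 7.10. Macrophage genes summed to 2016 ± 2468 against 290 ± 272 CPM (exact permutation p = 0.0857).

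**Figure D3:**
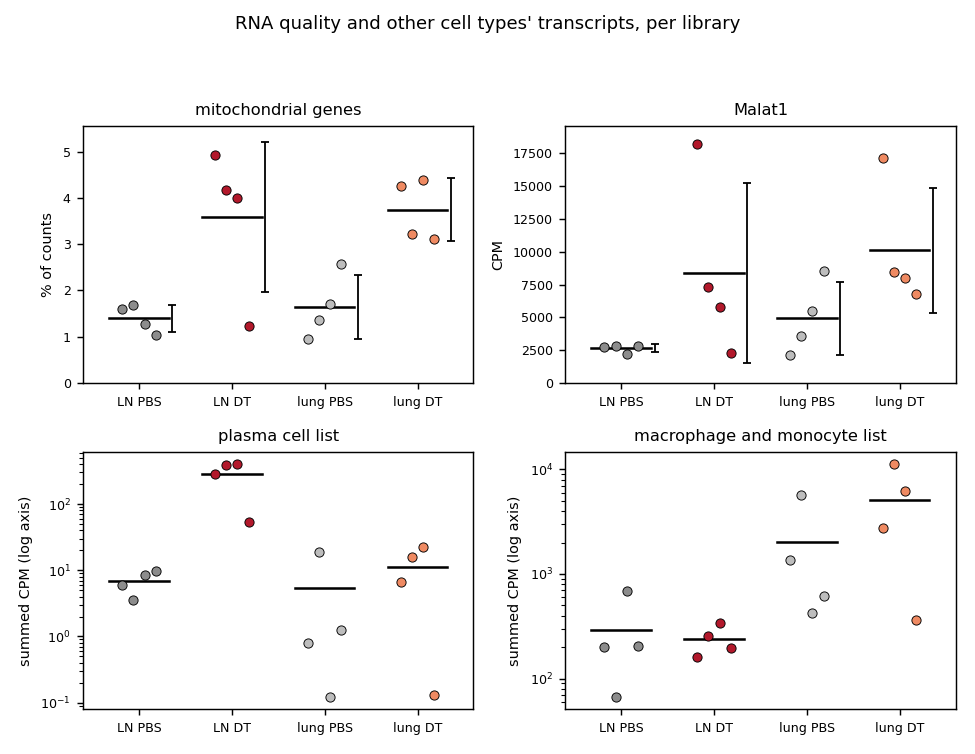
Quality measures and marker sums per library; the mitochondrial share is 1.4% and 3.59% in LN PBS and LN DT and 1.65% and 3.75% in lung PBS and lung DT (n = 4 each).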

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

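The tests of sequencing depth, of handling shared by the libraries numbered 1 and of plasma cell genes alone were chosen after the result was seen, and so were the 152 groups of values searched for libraries far from the rest. Leaving out the DT libraries numbered 1 and the mitochondrial covariate were chosen after those libraries had been seen to stand apart, and their counts of called genes had been seen before the tests of the mitosis list.

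The mitosis list was higher in the DT libraries of both tissues (median 1.18 in LN and 1.81 in lung), and division of NK cells after DT is a biological explanation that was not tested. With the summed genes of other cell types (T cells left out) as a covariate the medians were 1.16 and 1.69. This argues against RNA of the cell types that weigh most in that sum as the whole cause. Plasma cell genes weigh little in it: in LN DT they had 284 CPM against 2890 for B cells. In lung DT they had 11.3 CPM against 5148 for macrophages. RNA of T cells or plasma cells is therefore not excluded. With the mitochondrial share as a covariate the medians were 0.86 and 1.21, or 72.7% and 67% of the value. These lie between the bounds set for the test, so lower RNA quality could hold part of the rise and stays open. Without both DT libraries numbered 1 the median was 1.31 in LN, which argues against these libraries as its cause there, and 0.79 in lung, where 24 of 33 members lay above 0 and 43.4% of the value was left. These 3 tests had been worded for both tissues together, which leaves the question of the libraries numbered 1 undecided, and were read tissue by tissue only after the values were seen.

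Plasma cell genes summed to 284 ± 164 CPM in LN DT against 6.92 ± 2.80 in LN PBS (SD, n = 4), with 53.5 CPM in LN DT replicate 4; of the 8 genes of the list no other list holds any and 1 reaches 1 CPM in LN PBS. Of 41 tested immunoglobulin genes 39 (95.1%) had a log2 fold change above 0, with a median of 3.99, and at an unadjusted p under 0.05 27 were higher and 0 lower (edgeR called 2). This is consistent with RNA of plasma and B cells in the sort, which the NKp46+ DX5+ gate would remove, with Jchain at 201 ± 109 and Ighg1 at 301 ± 188 CPM. A lower share of NK cells would raise the markers of other cells alike. The ratio of B and plasma to macrophage genes, chosen first, did not separate the groups (difference 1.08 on the log2 scale, exact two-sided permutation p = 0.171). That is the outcome set in advance for a lower share, which is thus not excluded. The ratio of plasma to macrophage genes, added afterwards, was higher in 4 of 4 LN DT libraries (4.76, exact permutation p = 0.0286, the smallest possible). Plasma cell genes were by then known to separate the groups, so this p adds no support of its own. Macrophage genes had 238 ± 78.6 against 290 ± 272 CPM, but this PBS mean rests largely on LN PBS replicate 3 (685.5 CPM, others 66.4 to 205.5). Without that library the macrophage list rose (camera adjusted p = 0.0149). With or without it macrophage genes, at most 339.3 CPM in LN DT, rose less than plasma cell genes. This argues against that share as the whole cause of the plasma cell rise. Whether plasma cells grew in number in the nodes of mice given DT stays open and was not tested.

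The DT libraries numbered 1 stood apart on the second principal component, at 108 in LN and 152 in lung against at most 19.6 elsewhere, and held the highest mt-Cytb (32039 and 21697 CPM; others at most 8589), Malat1 (18216 and 17164; at most 8511) and share of the 20 most abundant genes (18.7% and 19.3%; at most 14.96%). Their total counts of 6657293 and 8317260 lie within the 3929560 to 10744934 of the other libraries, which argues against sequencing depth. Their deviations correlate with those of the PBS library numbered 1 of the same tissue by 0.0429 and 0.0165, which argues against handling shared by all libraries numbered 1. Their deviations correlate with each other by 0.41, so an animal or a step shared by these 2 libraries alone could lie behind both. Lower RNA quality of these libraries and a biological difference between mice stay open too, and neither was tested as the cause.

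In 18 of the 152 groups (11.8%) a library lay far from the other 3, where chance gives about 1 in 20. For AI593442 and Zfp882 the other 3 libraries are at 0, so any count stands out. These groups add nothing to the comparison with chance. For lung DT replicate 1 these were Malat1 at 17164 CPM (others 6813 to 8476), T cell genes at 1788 (1020 to 1110), Ifng at 1229 (126 to 287), Gzma at 38722 (10702 to 13531), Cd300lf at 218 (117 to 132), Top2a at 382 (94.6 to 118) and Zfp882 at 0.29 CPM with the others at 0. For lung PBS replicate 2 they were plasma cell genes at 19.1 CPM (0.121 to 1.24), neutrophil genes at 369 (76.7 to 87.6) and AI593442 at 0.28 (others at 0), and for lung PBS replicate 1 Cd69 at 503 (298 to 307). For LN PBS replicate 3 they were Malat1 at 2197 CPM (2733 to 2841), neutrophil genes at 16.9 (1.92 to 3.89), erythroid genes at 28.1 (1.21 to 1.58) and AI593442 at 0.12 (others at 0), and for LN PBS replicate 2 Ncr1 at 5326 (6102 to 6216). For LN DT replicate 4 it was Gzmb at 2539 CPM (1280 to 1493), and for LN DT replicate 1 Cd69 at 390 (389.62; others 141 to 156).

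A test of the difference between the LN and lung responses set Zfp882 apart, by 8.10 on the log2 scale, and 7 lists by camera: mature NK markers (adjusted p = 0.00102), inhibitory receptors (0.00726), cytotoxic effectors (0.0181), activating receptors (0.02), type I interferon genes (0.02), B cells (0.02) and cytokines (0.0382). With an estimated correlation their adjusted p ran from 0.294 to 0.814.

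Other splits of the libraries into groups of the same sizes were used to ask whether chance gives as many genes. For LN DT against PBS 1 of 35 splits, the real one, gave as many genes (9, highest other 0). For lung against LN in PBS mice it was again 1 of 35 (503, highest other 0). That is the fewest that 35 splits can give. The other splits mix the true groups, which adds to the spread and lowers their counts. The real split thus gave the most genes in both, but the splits alone cannot exclude chance. For lung DT against PBS 2 of 35 did (15, highest other 24), so chance cannot be excluded. The split with 24 genes sets lung PBS replicate 2 with lung DT replicates 1 to 3, and macrophage genes summed to 5667 CPM in that PBS library and 360.2 in lung DT replicate 4. For the difference of the responses 8 of 100 drawn regroupings did (1, highest other 587). In the 7 others the groups drawn as DT hold unequal numbers of true DT libraries in LN and lung, which leaves part of the DT responses themselves in the difference. Of the 36 with equal numbers the real one alone did, but the others mix DT and PBS libraries within groups, which adds to the spread. Whether chance can be excluded is therefore not decided here.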

How the results depend on the processing

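Chosen after seeing the data were 2 alternatives: leaving out both DT libraries numbered 1, and the mitochondrial share as a covariate. That share went largely with DT, so changes under this covariate cannot tell RNA quality from DT. No named gene reversed, and counts of genes or lists have no direction that could reverse. Of the lists, glycolysis passed in the opposite direction in 1 alternative in LN and in lung, as given below. No cause was tested for the changes below except where named. Total counts ran from 3929560 to 10744934, which left 13940 of 49671 genes with enough counts; in simulated data of this depth and spread 3.03% of 2-fold changes were recovered in LN and 1.49% in lung.

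Genes called in LN were 9 higher and 0 lower with median-ratio factors and with robust=FALSE, and 10 and 0 with total counts alone (9 shared) or a mean of at least 5 CPM (8 shared). No filter gave 23 higher (7 shared; 26329 genes tested), DESeq2 262 and 61 (9 shared), limma-voom with quality weights 2084 and 1652 (9 shared), the 8 LN libraries alone 38 and 3 (9 shared), no DT libraries numbered 1 22 and 2 (8 shared), and the mitochondrial covariate 1 and 0 (0 shared). Leaving out single libraries gave 0 to 74 higher and 0 to 48 lower: 1 without LN PBS replicate 1, 0 without LN PBS 3 or 4, 5 without LN DT 3, 74 and 48 without LN DT 4, 45 and 10 without lung DT 1, and 14 and 1 without lung DT 4. In edgeR with all libraries 491 genes were lower at an unadjusted p under 0.05. The cause was not tested; voom weights were lowest for LN DT 1 (0.266) and lung DT 1 (0.126).

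Genes called in lung, 8 higher and 7 lower, were 14 higher with a mean of at least 5 CPM (8 shared) and 12 lower with no filter. DESeq2 gave 275 and 181 (8 and 7 shared), limma-voom 251 and 184 (8 and 2 shared), the 8 lung libraries alone 0 and 0, no DT libraries numbered 1 169 and 305 (8 and 7 shared), and the mitochondrial covariate 0 and 1. In edgeR with all libraries 1068 were higher and 984 lower at an unadjusted p under 0.05. Leaving out single libraries gave 0 to 49 higher and 1 to 80 lower: 0 and 1 without lung PBS replicate 1 or 2, 1 and 4 without lung PBS 3, 1 and 5 without lung PBS 4, 20 and 24 without lung DT 1, and 49 and 80 without lung DT 4. There were 5 higher without LN PBS 2, 3 or 4 or LN DT 2 or 3. Lower genes were 4 without LN PBS 1, 3 without LN PBS 3 or 4 or LN DT 2 or 3, 15 without LN DT 1, 12 without lung DT 2 and 17 without lung DT 3. The cause was not tested.

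For the difference of the responses the 1 gene higher became 18 higher and 1 lower with DESeq2 and 0 with limma-voom, where edgeR had 401 and 185 at an unadjusted p under 0.05. Without single libraries there were 0 to 3: 0 without LN PBS replicates 2 to 4, LN DT 1 or 2, lung PBS 3 or 4 or lung DT 2 or 4, and 3 without lung DT 3. Between the tissues, 377 higher and 126 lower became 779 and 400 with DESeq2, 1241 and 1055 with limma-voom, 828 and 597 with the 8 PBS libraries alone and 902 and 460 without the DT libraries numbered 1, and 229 were lower with total counts alone. Without single libraries there were 206 to 675 higher and 56 to 317 lower: 224 and 68 without LN PBS replicate 1, 234 and 66 without LN PBS 3, 206 and 62 without LN PBS 4, 675 and 317 without lung DT 1, and 74, 64, 56 and 77 lower without lung PBS 1 to 4. The cause was not tested. Genes changed the same way in both tissues after DT, 2 at an adjusted p under 0.05, numbered 8 under 0.1 (7 higher and 1 lower).

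Lists past the threshold in LN, 11 in the main test, were 1 with an estimated correlation (immature markers) and 3 with fry (mitosis, inhibitory receptors and immature markers). In lung, 3 became 7 without the DT libraries numbered 1, 6 with the mitochondrial covariate and 0 with an estimated correlation or fry, and 3 to 10 without single libraries: 7 without LN PBS replicate 3, LN DT 1 or 2 or lung PBS 4, 5 without LN DT 4 or lung PBS 3, 6 without lung PBS 2, 8 without lung DT 1 and 10 without lung DT 4. For the difference, 7 became 0 with an estimated correlation or fry, and 3 to 10 without single libraries, with 3 without lung DT 3; between the tissues 12 became 4 with an estimated correlation. Mitosis passed in 22 of 22 alternatives in LN (camera adjusted p 3.91e-16 to 4.65e-07) and in lung (6.19e-15 to 1.33e-04), as did inhibitory receptors (1.33e-07 to 0.0275) and immature markers (1.19e-05 to 0.00202) in LN and DNA replication in lung (2.72e-06 to 0.0141). With an estimated correlation mitosis passed in 0 of the 22 in LN (0.11 to 0.387) and lung (0.195 to 0.608), inhibitory receptors in 0 (0.0511 to 0.534), immature markers in 13 and DNA replication in 0 (0.212 to 0.677). Of lists that had not passed, ILC1 markers did for the difference in 13 of 22 alternatives, and in lung oxidative phosphorylation in 11, glycolysis in 9 and cytotoxic effectors and MYC in 7 each. The glycolysis list passed upward with the mitochondrial share as a covariate in LN (0.00562) and lung (0.00693), where the test had pointed down. Named genes that passed missed the threshold in 23 of 135 alternatives in LN, 79 of 270 in lung, 11 of 26 for the difference and 125 of 1537 between the tissues. Named genes that had not passed did so in 130 of 1836, 97 of 1941, 2 of 1638 and 76 of 675.

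With the replicate number as a block the counts were 7 higher and 0 lower in LN (6 shared), 9 and 4 in lung (6 and 4 shared), 0 for the difference and 408 and 130 between the tissues, and 6 lists passed in lung. The immature list in LN then missed the threshold with an estimated correlation (0.0694; 0.0145 to 0.0922 over all alternatives). The labels do not say that numbers pair the samples. As a hint from the data, not the design, deviations of libraries with the same number correlated by 0.0429, 0.145, 0.0961 and 0.0295 (LN DT with LN PBS), 0.0165, 0.207, -0.127 and 0.0818 (lung DT with lung PBS), -0.0224, 0.191, -0.0303 and -0.00119 (the PBS groups) and 0.412, 0.194, 0.23 and 0.184 (the DT groups). Not every sample correlates best with its own number: LN DT replicate 2 had 0.229 with lung DT replicate 3. The DT groups of the 2 tissues are above 0.1 in all 4 pairs and the PBS groups are not, and the overlap of the tissues and the test of their difference take all libraries as independent.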

Other observations

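The genes named in the first 3 paragraphs were chosen after their values were seen. The maturation hypothesis was written after the camera results of its lists had been seen, and the test of mature markers alone was added after the other result was seen.

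Genes outside the fixed lists, and Kit of the immature marker list, also separated lung from LN NK cells in mice given PBS. The cell cycle inhibitor gene Cdkn1a rose by 5.84 ± 0.38 on the log2 scale (SE, n = 4; adjusted p = 1.87e-07), from 8.04 ± 1.78 to 461 ± 57.7 CPM (SD). Higher in lung were also Crem (4.80, adjusted p = 1.05e-06), Sik1 (5.66, 6.25e-06) and Pde4b (1.63, 4.31e-04), which take part in cyclic AMP signalling. Of regulators of stress and transcription, Sgk1 (2.80, adjusted p = 2.14e-05), Fosl2 (4.24, 4.73e-06), Kdm6b (2.60, 1.64e-04) and Hes1 (3.45, 1.92e-04) rose. Lower in lung were the receptor genes Cd160 (-1.90, adjusted p = 3.20e-04), Kit (-2.54, 0.00987) and Gpr183 (-1.62, 0.0166), the ligand genes Vegfc (-2.73, 0.00654) and Tnfsf14 (-2.23, 0.0122), and the small GTPase genes Gimap5 (-1.02, 0.0259) and Gimap7 (-1.68, 0.0390).

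After DT, several genes lay near the threshold without passing. In LN Vmp1, of autophagy, stood at 2282 ± 1883 against 415 ± 96.8 CPM (SD, n = 4; adjusted p = 0.0633) and the protease inhibitor gene Slpi at 58.4 ± 46.3 against 1.18 ± 1.47 (0.0766). Ccl9, a chemokine gene, stood at 30.1 ± 15 against 5.86 ± 1.78 CPM in LN (adjusted p = 0.0766) and at 148 ± 66.4 against 45.3 ± 26.7 in lung (0.122). In lung the condensin gene Ncapg2 stood at 60.6 ± 11.5 against 9.14 ± 5.06 CPM (adjusted p = 0.0623), the uridine phosphorylase gene Upp1 at 28.4 ± 18.1 against 2.96 ± 1.96 (0.0623) and Abcb1b, a transporter, at 93.5 ± 28.6 against 24.4 ± 14.6 (0.0762). The giant muscle gene Neb stood at 9.31 ± 5.41 against 0.58 ± 0.21 CPM in lung (0.0701).

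Lists of other cells with too few tested members for camera were compared by their summed CPM with exact two-sided permutation tests. Such a sum can rest mostly on a single gene. In the regulatory T cell sum Capg held 283 CPM in LN DT and 193 in LN PBS. Foxp3 itself had 0.877 ± 0.377 and 0.265 ± 0.458 CPM (SD). In the endothelium sum Pecam1 held 99.2 CPM in LN DT and 121 in LN PBS. In LN DT against LN PBS the sums were 362 against 250 CPM for regulatory T cell genes (p = 0.0571), 8.16 against 3.32 for mast cells and basophils (0.114), 20.5 against 7.20 for ILC2 and ILC3 (0.0857), 6.26 against 11.9 for lung epithelium (0.771), 102 against 122 for endothelium (0.429), 2.13 against 2.37 for fibroblasts (0.943) and 22.7 against 8.05 for erythroid cells (exact permutation p = 0.2). In lung DT against lung PBS they were 301 against 223 CPM for regulatory T cell genes (exact permutation p = 0.6), 18.8 against 7.93 for mast cells and basophils (0.343), 11 against 5.08 for ILC2 and ILC3 (0.171), 79.2 against 25.7 for lung epithelium (0.4), 6.16 against 2.85 for mammary and keratin genes (0.686), 150 against 89.8 for endothelium (0.143), 9.21 against 11 for fibroblasts (0.714), 280 against 642 for erythroid cells (0.143) and 11.3 against 5.33 for plasma cells (0.343). Mammary and keratin genes summed to 268 CPM in LN PBS replicate 3, with Lcn2, Krt18 and Krt8 the most abundant, and to at most 0.226 in the other LN PBS libraries (exact permutation p = 0.971 for LN DT against PBS).

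A hypothesis is that LN NK cells shift toward the mature state after DT. The mean log2 CPM of mature minus immature markers was 1.16 ± 0.21 in LN DT and 0.21 ± 0.37 in LN PBS (SD, n = 4; difference 0.95), higher in 4 of 4 LN DT libraries than in any LN PBS library (exact two-sided permutation p = 0.0286, the smallest possible). The measure was 3.44 ± 0.28 in lung PBS and 3.58 ± 0.31 in lung DT, and 9 of 15 mature and 9 of 16 immature genes are in another list as well. That score holds the immature list whose fall raised the question, so it cannot decide. Mature markers alone had a mean log2 CPM of 8.17 ± 0.21 in LN DT and 7.82 ± 0.34 in LN PBS (difference 0.35; 1 of 4 LN DT libraries above every LN PBS library; exact permutation p = 0.143; camera adjusted p = 0.0957), which does not separate the groups. Their list rose in 3 of 22 alternatives: without LN PBS replicate 2 (camera adjusted p = 0.0148), without both DT libraries numbered 1 (0.0126) and with the mitochondrial share as a covariate (1.40e-04), within 1.40e-04 to 0.566 over all. The hypothesis stays open.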
